A study of Homo sapiens with 10 samples.

How the data were processed

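RNA was measured by sequencing in hCMEC/D3, an immortalised human brain microvascular endothelial cell line that is widely used as a model of the blood-brain barrier. The 10 libraries fall into 5 groups of 2: sham, hematoma, atorvastatin, dexamethasone and the combination of both drugs. Per the labels' protocols, the supernatant of hematoma fluid from patients with chronic subdural hematoma was mixed with buffer or with drug and kept on the cells for 1 h, after which the cells went to normal medium without drug. Drug doses, the time between treatment and harvest and the handling of the sham cells are not given in the sources used here. The series title calls the dexamethasone of the combination low, so the combination was not treated as a matched-dose mixture of the single treatments. Groups were taken from the treatment named in the labels. The names of both hematoma columns end in a number, as all columns do, but do not show which hematoma sample of the labels each one holds. These libraries were therefore given no replicate number and are called a and b. Nothing in the labels says whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

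The deposited table gives FPKM values (fragments scaled by the authors for gene length and library depth) for 29721 genes in each library, with gene symbols, biotypes and gene ontology terms. Libraries were made with a NEBNext Ultra RNA kit, per the labels. Alignment used HISAT2 2.1.0, per the submitters' processing notes. The read counter, its use of strand and the genome build are not given in the sources used here. The table's gene positions equal those of GENCODE release 29 for 29676 of the 29721 genes, so positions are printed as the table gives them. A second deposited table held the same 297210 FPKM values without gene names and was not used.

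Depth was recomputed from the FPKM values. Each non-zero value, multiplied by the summed exon length of its gene in GENCODE release 29, was a whole multiple of a step fixed for the library, within 0.01 steps, for 100.0% of values in every library. The step was taken as 1 read. This gave 16201861 to 18411429 reads per library, and 1 read in a gene of 1 kb stood for 0.0543 to 0.0617 FPKM. Even read numbers were about as frequent as neighbouring odd ones (ratio 0.99). The FPKM values stayed the main data, as planned for FPKM, and the recomputed reads served for alternatives and checks. Between the libraries of a group, reads differed by a mean chi-square of 1.84 to 2.5 per gene over genes with at least 20 reads in the pair. That is more than the value of 1 that sampling alone gives, and each library was kept as its own replicate.

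Values were analysed as log2(FPKM + 1) with R 4.3.3 and limma 3.58.1, and fold changes are on that scale, which understates the change of low genes. Python 3.11.15 read the table. The 11624 genes with a mean of at least 1 FPKM over the 10 libraries were tested. A linear model with 5 group means was fitted to all 10 libraries, so that the groups shared 1 estimate of the spread (5 residual degrees of freedom, 3.34 prior degrees of freedom, variance trend on mean expression). Tests were two-sided, adjusted by Benjamini-Hochberg within each of 7 comparisons, with a threshold of 0.05 on the adjusted p. The comparisons were hematoma against sham, each of the 3 treatments against hematoma, the combination against each single drug, and the interaction. The interaction is the log2 change from dexamethasone to combination minus that from hematoma to atorvastatin, which is the departure from additivity of the treatments as given.

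Before the data were examined, 29 gene lists were fixed for pathways and cell types that fit the cells and treatments. Lists with at least 5 tested members, 25 in all, were tested with limma's camera, which compares the list with all other genes, at a preset correlation of 0.01 between genes, and again with the correlation estimated from the residuals. List p-values were adjusted over the lists of a comparison. In the main fit, a called list given with the preset p-value alone also passed with the estimated correlation, at a larger p-value. The lists of erythroid, leukocyte, mural and astrocyte or neuron markers had 1, 3, 3 and 3 tested members and were described by their values. The results of 1 of the 25 lists and of some of the genes the rule below names are not reported here. Named genes followed a rule fixed at the same time. For each comparison it took the 12 largest rises and 12 largest falls in log2 fold change among genes past the threshold with a gene symbol, a mean of at least 5 FPKM in the higher group and no overlap between the libraries of both groups. The condition on overlap was left out for the interaction. Where fewer than 5 genes passed, it added the 5 lowest p-values. It also took up to 4 tested members of each list described, and genes named in advance for dexamethasone, atorvastatin, hematoma and junctions.

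Comparisons that share the hematoma libraries share their chance values. Overlaps of calls were set beside the overlap of independent calls, and the covariance of the changes beside 100 simulations in which the treatments left the cells unchanged. The steps were first tested on simulated reads for the real genes, with 200 of 11624 changed, and a list of 20 others raised 1.2-fold, at a dispersion of 0.00254 for all genes. The 200 were drawn from genes with a mean of at least 5 FPKM, so the shares recovered do not hold for lower genes. In the simulated dexamethasone comparison, of the 200, 7.46% of genes changed 1.2-fold, 92.5% of those changed 1.5-fold and 97% of those changed 2-fold were called. Of the 137 calls, those in the list of 20 included, 2.92% were false. In the simulated combination comparison those shares were 13.4%, 97% and 100%, with 4.7% of 149 calls false.

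Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, quantile normalization, fits to the groups compared alone, the replicate number as a block, each library left out in turn, and the estimated correlation for lists. Chosen after the data were seen were scaling to reads outside the mitochondrial genome and limma's voom on the recomputed reads. Enrichment of gene ontology terms of the deposited table, by one-sided Fisher's exact test over 9427 annotated genes and 1482 terms of 10 to 300 genes, was also chosen after the data were seen. Genes listed as pseudogenes, short RNAs under other genes and antisense genes can share reads with their neighbours or parent genes, and their values are uncertain.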

Results

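RNA abundance was measured by sequencing in hCMEC/D3 cells, an immortalised line of human brain microvascular endothelial cells. There were 5 groups of 2 libraries: sham cells, which serve as the background, and cells exposed to hematoma supernatant with buffer, with atorvastatin, with dexamethasone or with both drugs. Atorvastatin is a statin, a drug that inhibits cholesterol synthesis, and dexamethasone is a glucocorticoid receptor agonist. The recomputed depth was 18411429 and 18334151 reads in the sham libraries, 17827524 and 17933640 in the hematoma libraries, and 17234161 and 18244840 in the atorvastatin libraries. It was 17121147 and 16201861 reads in the dexamethasone libraries and 17613987 and 18361108 in the combination libraries. Abundance is given as mean FPKM ± SD (n = 2 libraries), and changes as log2 fold changes of FPKM + 1 with adjusted p-values from limma.

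The sham libraries stood apart from all others, and the combination libraries stood apart from the remaining ones. The first principal component held 57.8% of the variance and the second 16.7%. Correlations across genes between the libraries of a group were 0.9931 to 0.9934, and genes are not independent replicates. Genes of the mitochondrial genome took 3.53% ± 0.01 of reads in sham, 5.88% ± 0.04 in hematoma, 5.75% ± 0.03 in atorvastatin, 5.7% ± 0.04 in dexamethasone and 4.77% ± 0.17 in combination libraries (SD, n = 2). Markers of other cell types were mostly near 0. The leukocyte gene PTPRC reached at most 0.00608 FPKM and the haemoglobin gene HBA1 at most 0.0328 FPKM in any group, while the erythroid list's only tested member, SLC25A37, was at 12.2 FPKM in sham and 8.37 FPKM in hematoma libraries. CD14, a monocyte marker that endothelial cells can express, was at 0.534 FPKM in sham and 1.85 FPKM in hematoma libraries. The leukocyte markers LAPTM5 and CORO1A were at 11 and 0.475 FPKM in sham and at 12.5 and 1.19 FPKM in hematoma libraries. The mural markers PDGFRB, CSPG4 and ACTA2 were at 2.6, 2.34 and 1.67 FPKM in sham and at 0.259, 1.28 and 1.18 FPKM in hematoma libraries, while MCAM, a mural marker that endothelial cells also express, was at 67 and 93.4 FPKM, and at 117 FPKM in combination libraries. The astrocyte marker GJA1, also an endothelial gene, lay between 37.3 and 42 FPKM in all groups, and MBP and MAP2 were at 3.9 and 2.44 FPKM in sham and at 2.57 and 1.22 FPKM in hematoma libraries.

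**Figure D1:**
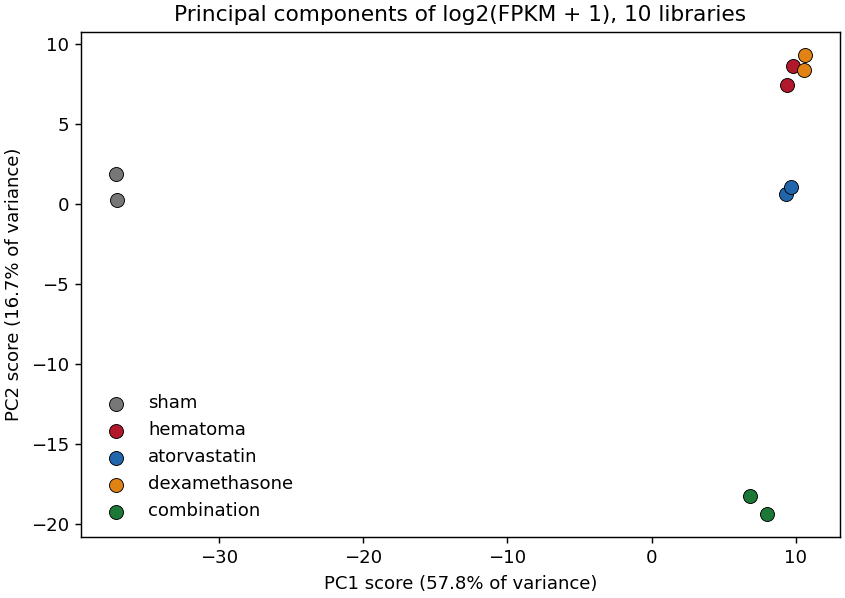
Each point is 1 of the 10 libraries, placed by its first and second principal component over log2(FPKM + 1) of 11624 genes, with colours for the 5 groups. The sham libraries lie at -37.07 and -37.17 on the first component, the others between 6.83 and 10.65, and the combination libraries lie at -18.25 and -19.36 on the second.

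The comparison of hematoma with sham asks how cells exposed to hematoma supernatant differed from sham cells. The handling of the sham cells is not given, so a handling difference cannot be told apart from the exposure. In hematoma libraries the phosphatase gene DUSP23 and the growth factor CSF3 rose most, the stress and autophagy gene SQSTM1 fell about 4-fold, interferon response genes fell together, and glucocorticoid receptor targets and transcripts of the mitochondrial genome rose. DUSP23 (ENSG00000158716, chromosome 1, 159780932 to 159782543), rose from 21.6 ± 0.122 to 168 ± 0.926 FPKM (log2 fold change 2.90, SE 0.04, adjusted p = 1.6e-09). CSF3, the granulocyte colony-stimulating factor (ENSG00000108342, chromosome 17, 40015361 to 40017813), rose from 1.43 ± 0.126 to 16.6 ± 0.322 FPKM (2.85, adjusted p = 6.2e-09). SQSTM1, which encodes the autophagy receptor p62 (ENSG00000161011, chromosome 5, 179806398 to 179838078), fell from 115 ± 1.6 to 27.3 ± 0.33 FPKM (-2.04, SE 0.03, adjusted p = 1.6e-09). TNFSF18, the ligand of the receptor GITR (ENSG00000120337, chromosome 1, 173039960 to 173050963), fell from 20.2 ± 0.668 to 2.71 ± 0.639 FPKM (-2.52, SE 0.11, adjusted p = 3.9e-07). The other largest rises had log2 fold changes of 2.79 for ID1, 2.66 for ETV4, 2.62 for SLCO2A1, 2.61 for CHAC1, 2.60 for AREG, 2.59 for STC1, 2.44 for CA2, 2.28 for IGFBP4, 2.12 for ETV5 and 2.11 for LTBP1. ID1 encodes an inhibitor of DNA binding induced by BMP signals, SLCO2A1 a prostaglandin transporter and AREG a ligand of the EGF receptor. The other largest falls were -2.50 for BMF, -2.48 for TRIM16L, -2.45 for DEPP1, -2.25 for PPL, -2.24 for ANKRD1 and CPA4, -2.22 for LTB, -2.16 for YPEL3 and -2.13 for HDAC5.

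In hematoma libraries, 23 of 25 interferon response genes fell and none rose (median log2 fold change -0.73, camera adjusted p = 2.1e-10, and 0.017 with an estimated correlation). RSAD2, an antiviral enzyme induced by interferon, fell from 49.5 ± 1.13 to 13.1 ± 0.889 FPKM, and IFIT2, USP18 and IRF7 fell by 1.25, 1.01 and 0.98 on the log2 scale. Of 19 NRF2 and haem response genes 14 fell and 2 rose (median -0.52, adjusted p = 2.7e-04). Among them were TXNRD1 at -1.56, the ferritin light chain FTL at -1.33, and HMOX1, which degrades haem and is commonly induced by it, at -1.16 (36.1 ± 0.107 to 15.6 ± 0.543 FPKM, adjusted p = 1.3e-06). Glucocorticoid receptor targets were higher for 16 and lower for 4 of 20 (median 0.53, adjusted p = 5.9e-06). FKBP5, a co-chaperone of that receptor (ENSG00000096060, chromosome 6, 35573585 to 35728583), rose from 20.5 ± 0.112 to 59.7 ± 0.481 FPKM (1.5, adjusted p = 7.5e-09). DDIT4, MT2A, PER1 and TSC22D3 rose by 1.85, 1.68, 1.35 and 1.28.

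Of 13 mitochondrially encoded genes 12 rose (median 1.07, adjusted p = 5.2e-11), with MT-CO3 going from 2055 ± 23 to 7653 ± 2.54 FPKM, as the mitochondrial share of reads went from 3.53% to 5.88%. Unfolded protein and integrated stress response genes rose for 15 and fell for 3 of 19 (median 0.48, adjusted p = 7.5e-06). PSAT1 rose by 1.44 and XBP1 by 1.01, while PPP1R15A was at -1.45. DNA replication genes rose for 15 and fell for 2 of 23 (median 0.27, adjusted p = 9.2e-06), among them CDC45 at 0.89 and CCNE1 at 0.82. Cell cycle genes of the G2 and M phases fell for 21 of 22 (median -0.34, adjusted p = 5.2e-06), among them HMMR at -0.73 and KIF20A at -0.68, with an adjusted p = 0.065 at an estimated correlation. Endothelial identity genes rose for 11 and fell for 1 of 17 (median 0.26, adjusted p = 7.3e-05), among them EGFL7 at 1.34, the VEGF receptor KDR at 1.28, and ENG at 0.90.

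Targets of YAP and TAZ, transcriptional regulators that respond to cell shape and tension, fell for 13 and rose for 3 of 19 (median -0.49, adjusted p = 0.0025). The matricellular gene CYR61 fell by 1.64 and TGFB2 by 1.61. Targets of p53 fell for 16 and rose for 2 of 19 (median -0.53, adjusted p = 0.0023), among them BBC3 at -1.26 and CDKN1A, an inhibitor of the cell cycle, at -0.88. With an estimated correlation both lists had an adjusted p = 0.12. All 5 metallothionein genes past the threshold, of 6, rose (median 0.87, adjusted p = 3.7e-04, adjusted p = 0.15 with an estimated correlation). Heat shock genes rose for 8 and fell for 5 of 16 (median 0.17, adjusted p = 0.041, and 0.13 with an estimated correlation), with HSPD1 at 0.89 and HSPA1A at -0.77. Angiogenic factors and receptors rose for 9 and fell for 5 of 17 (median 0.43, adjusted p = 0.038, and 0.15 with an estimated correlation), with ANGPTL4 at 1.18. Quantile normalization ended the calls of the heat shock list (adjusted p = 0.25) and the angiogenic list (adjusted p = 0.086).

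The remaining lists were not past the threshold. Tight and adherens junction genes were higher for 3 and lower for 13 of 20 (median -0.18, adjusted p = 0.089), and quantile normalization brought the list past the threshold (adjusted p = 0.027). In it OCLN, a tight junction protein, fell by 0.71, its scaffold TJP1 by 0.42 and the endothelial cadherin CDH5 by 0.29, while PECAM1 rose by 0.69. CLDN5, the main claudin of brain endothelium, was low at 0.548 ± 0.0769 and 1.06 ± 0.272 FPKM (0.41, adjusted p = 0.018). NF-kB inflammatory genes went both ways, 6 higher and 13 lower of 22 (median -0.32, adjusted p = 0.61), with BIRC3 at 1.2, ICAM1 at 0.28, CXCL8 at -0.38 and TNFAIP2 at -1.68. Cholesterol synthesis genes were higher for 5 and lower for 9 of 23 (median -0.05, adjusted p = 0.99), with HMGCS1 at -0.44 and INSIG1 at -0.32. Medians and adjusted p were 0.06 and 0.21 for fatty acid synthesis, and 0.00 and 0.81 for the programme of the flow-induced factors KLF2 and KLF4. They were 0.15 and 0.24 for immediate early genes, -0.30 and 0.99 for hypoxia and glycolysis, and -0.02 and 0.86 for blood-brain barrier transporters. They were 0.18 and 0.13 for coagulation and fibrinolysis, -0.15 and 0.99 for TGF-beta and matrix genes, and -0.04 and 0.39 for cytosolic ribosomal proteins. For the ribosomal list, quantile normalization gave -0.11 and 0.0015.

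In all, 7148 of 11624 genes differed between hematoma and sham libraries, 2678 higher and 4470 lower, and of these 174 rose and 227 fell at least 2-fold. The median of all genes was -0.098, and quantile normalization, which moved it to -0.017, gave 3244 higher and 3447 lower genes. In all, 13 of 25 lists passed the threshold, 7 of them with an estimated correlation. Counts adjusted over the list alone were the same, except for 13 lower ribosomal genes in place of 14. The call of CLDN5 ended without sham library 2 (adjusted p = 0.086), without hematoma library b (0.12), without a filter and in the groups compared alone (0.059 in both).

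Atorvastatin against hematoma asks what the statin changed in exposed cells. The flow-responsive transcription factor KLF2 rose about 7-fold and RHOB about 3-fold, interferon response and NF-kB inflammatory genes rose, the YAP targets CTGF, ANKRD1 and CYR61 fell, and cholesterol synthesis genes showed no joint change. KLF2 (ENSG00000127528, chromosome 19, 16324817 to 16327874) rose from 7.43 ± 0.243 to 59 ± 5.77 FPKM (log2 fold change 2.83, SE 0.08, adjusted p = 2.2e-06) and stood at 5.93 ± 0.288 FPKM in sham libraries. RHOB (ENSG00000143878, chromosome 2, 20447074 to 20449445) rose from 32.2 ± 0.515 to 101 ± 3.06 FPKM (1.62, SE 0.06, adjusted p = 5.8e-06). CTGF, a matricellular YAP target (ENSG00000118523, chromosome 6, 131948176 to 131951373), fell from 132 ± 4.41 to 61.2 ± 1.8 FPKM (-1.09, SE 0.04, adjusted p = 5.8e-06). The cytoskeletal actin ACTG1 fell from 975 ± 1.63 to 687 ± 7.69 FPKM (-0.50, adjusted p = 2.5e-05). Other large falls were APLN at -0.95, ANKRD1 at -0.85, CYR61 at -0.65, DKK1 at -0.61, FAM43A at -0.50, CLDN11 and SCARF2 at -0.47, CHAC1 and MYL9 at -0.46, and the ribosomal pseudogene RPL9P7 at -0.54. Other large rises were IL6 at 0.74, SAA1 and CSF3 at 0.73, CMPK2 at 0.71, RSAD2 and NDRG1 at 0.66, SAMD9 at 0.64, TYMP at 0.63 and TNFSF10 at 0.61. The small RNA pseudogene RNU6-1091P was at 1.13.

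With atorvastatin, 22 of 25 interferon response genes rose and none fell (median 0.39, camera adjusted p = 2.9e-40, and 5.7e-04 with an estimated correlation). IFI6 rose from 946 ± 10.7 to 1304 ± 8.9 FPKM, beside 1410 ± 24 FPKM in sham libraries, and IFIT2 and MX2 rose by 0.55 and 0.47. The KLF2 and KLF4 programme rose for 8 of 10 genes (median 0.38, adjusted p = 1.3e-14), with THBD, the anticoagulant receptor thrombomodulin, at 0.49 and KLF6 at 0.47. NF-kB inflammatory genes rose for 11 of 22 (median 0.28, adjusted p = 6.0e-10, and 0.035 with an estimated correlation). CXCL2 was at 0.52, IL1B at 0.50 and CXCL8 at 0.30, while ICAM1 stayed at 0.03 and was not past the threshold. The NF-kB list also shifted up with dexamethasone against the same hematoma libraries (median 0.11). Part of its rise with atorvastatin can therefore come from those libraries. Immediate early genes rose for 6 and fell for 2 of 18 (median 0.13, adjusted p = 1.3e-04), with JUNB at 0.32 and KLF10 at 0.30. Targets of YAP and TAZ fell for 5 of 19 (median -0.10, adjusted p = 4.1e-06, and 0.053 with an estimated correlation), with FJX1 at -0.37 beside CTGF, ANKRD1 and CYR61. Glucocorticoid receptor targets rose for 4 and fell for 1 of 20 (median 0.07, adjusted p = 3.3e-04, and 0.057 with an estimated correlation). Of these TSC22D3, which encodes the anti-inflammatory protein GILZ, rose by 0.56, DUSP1 by 0.40 and KLF9 by 0.38, while FKBP5 at 0.03 and PER1 at 0.06 were not past the threshold.

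Small falls were called for unfolded protein and integrated stress response genes (4 of 19 lower, median -0.03, adjusted p = 0.014), with PSAT1 at -0.38, STC2 at -0.27 and TRIB3 at -0.25. They were called for G2 and M genes (1 of 22 lower, PLK1 at -0.20, median -0.04, adjusted p = 0.0086) and cytosolic ribosomal proteins (3 of 32 lower, RPLP0, RPL4 and RPL3, median -0.05, adjusted p = 3.5e-04). With an estimated correlation these 3 lists had an adjusted p of 0.10, 0.21 and 0.32. Of 23 cholesterol synthesis genes, the list a statin would act on through SREBP2, DHCR7 alone passed, at -0.22 (median 0.00, adjusted p = 0.49). HMGCS1 at 0.13 and INSIG1 at -0.14 were not past the threshold. In the junction list 2 of 20 genes fell, CLDN11 at -0.47 among them, and none rose (median 0.03, camera adjusted p = 0.29). Of that list CLDN5 at 0.48 (adjusted p = 0.069), TJP1 at 0.14, CDH5 at 0.03 and OCLN at -0.04 were not past the threshold. HMOX1, which is outside it, was at -0.16 and did not pass either.

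In all, 485 genes passed, 326 higher and 159 lower, of which 5 rose and 3 fell at least 2-fold, and 9 of 25 lists passed, 4 of them with an estimated correlation. Adjusted over the list alone, more genes passed in several lists, with 14 NF-kB, 23 interferon, 9 KLF2 and KLF4, and 10 higher and 3 lower immediate early genes, and 10 lower and 1 higher YAP and TAZ targets. Fewer genes passed when any 1 hematoma or atorvastatin library was left out. Such a fit has less power, so the drop does not single out a library. Without a filter 280 passed, in the groups compared alone 156, and with voom 986. At least 1 left-out library or other setting ended the calls of RNU6-1091P, SAA1, DKK1, RPL9P7, FAM43A, SCARF2, TYMP, CXCL8, CXCL2, IL1B, FJX1, JUNB, KLF10, THBD, DHCR7, PSAT1, STC2, TRIB3, PLK1, RPLP0, RPL4 and RPL3. Leaving out hematoma library a ended all of these but CXCL2 and JUNB, with adjusted p from 0.052 for KLF10 to 0.20 for RNU6-1091P. The highest adjusted p was 0.21 for RPLP0 without hematoma library b, 0.15 for RPL9P7 without atorvastatin library 1, and 0.21 for SCARF2 without atorvastatin library 2.

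Of the genes called in both comparisons, 280 had changed in opposite directions with hematoma and with atorvastatin, and 139 in the same direction. Of the 280, 195 had been lower in hematoma than in sham libraries, such as RSAD2 and IFI6, and rose with atorvastatin (expected 125 for independent calls), and 85 went the other way (expected 36.6). Both comparisons use the hematoma libraries with opposite sign, which alone gives opposite changes. The covariance of the changes was -0.0143, against -0.00616 in simulated groups that atorvastatin left unchanged. In the real data with 1 hematoma library in each comparison, and none shared, the covariance was -0.00539 and the correlation -0.06. Sharing adds nothing to those values, but it gave part of the -0.0143. Without a filter 174 genes changed in opposite directions, with voom 559, and 125 to 215 with 1 library left out.

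Dexamethasone against hematoma asks the same of the glucocorticoid. With dexamethasone the cells lay close to the hematoma libraries: 1 of 11624 genes passed, and the glucocorticoid receptor targets FKBP5, TSC22D3 and PER1 did not. The gene that passed was RPL39P36, a ribosomal protein pseudogene (ENSG00000239912, chromosome 19, 53413190 to 53413345), at 0.359 ± 0.0015 FPKM in hematoma and 2.51 ± 0.37 FPKM in dexamethasone libraries (log2 fold change 1.36, SE 0.10, adjusted p = 0.0053), beside 2.62 ± 0.255 FPKM in sham libraries. It can share reads with its parent gene. FKBP5 went from 59.7 ± 0.481 to 62.2 ± 0.756 FPKM (0.06, 95% interval -0.01 to 0.13, adjusted p = 0.62), TSC22D3 from 12.8 ± 0.278 to 13.9 ± 0.17 FPKM (0.11, interval 0.02 to 0.20, adjusted p = 0.48), and PER1 stood at 0.03 (interval -0.10 to 0.16).

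The lists showed small joint shifts with dexamethasone, in genes that were not past the threshold one by one. Over all genes, the changes with dexamethasone and with atorvastatin had a covariance of 0.00942, against 0.00615 in simulated groups that both drugs left unchanged. Their correlation was 0.40, against 0.50 in those simulated groups. With no hematoma library shared the covariance was 0.000486 and the correlation 0.02. List shifts common to both drugs can therefore come from the shared hematoma libraries. Interferon response genes had a median of 0.08 (adjusted p = 4.1e-12, and 0.011 with an estimated correlation), with IFI6 at 0.17, and 12 of 25 were higher when adjusted over the list alone. NF-kB inflammatory genes had a median of 0.11 (adjusted p = 1.9e-07, and 0.064 with an estimated correlation), with 8 of 22 higher when adjusted over the list alone, CXCL2 at 0.46 and CXCL8 at 0.25. Glucocorticoid receptor targets had a median of 0.05 (adjusted p = 0.030, and 0.21 with an estimated correlation), with 1 of 20 higher over the list alone and DUSP1 at 0.15. Endothelial identity genes had a median of -0.09 (adjusted p = 1.8e-04, and 0.072 with an estimated correlation), with 3 of 17 lower over the list alone, MMRN2 at -0.22 and CDH5 at -0.15. The medians were -0.05 for TGF-beta and matrix genes (adjusted p = 1.1e-04), -0.05 for cytosolic ribosomal proteins (4.4e-06), -0.03 for G2 and M genes (0.0019), -0.04 for coagulation and fibrinolysis (0.0062), 0.03 for heat shock genes (0.038) and 0.07 for immediate early genes (0.035). With an estimated correlation these 6 lists had adjusted p of 0.064, 0.24, 0.21, 0.24, 0.21 and 0.21. The mitochondrial list passed downwards (0.038, and 0.24 with an estimated correlation) with a median of -0.01 and a mean of 0.03, so its sign differs between measures. Quantile normalization ended the calls of the ribosomal list (0.064) and the mitochondrial list (0.50).

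limma called 1 gene, 1051 had an unadjusted p under 0.05, and voom called 92. Further genes of low p, none past the threshold, were CXCL1 at 0.36 (adjusted p = 0.064), VAMP8 at -0.23 (0.10) and the short RNA RNY4P19, listed at 0 FPKM with dexamethasone (0.064). The same steps recovered 92.5% of genes changed 1.5-fold and 7.46% of those changed 1.2-fold in simulated reads for this comparison. There 200 genes with a mean of at least 5 FPKM were changed, so these shares do not carry over to lower genes or to fewer changed genes. Without hematoma library a 2 genes passed, and without hematoma library b or without dexamethasone library 2 none did. The call of RPL39P36 ended without hematoma library b (0.094), without dexamethasone library 2 (0.075), in the groups compared alone (0.19) and with voom (0.25). HMGCS1, INSIG1, HMOX1, ICAM1, CLDN5, OCLN and TJP1 were not past the threshold, at 0.10, -0.29, 0.07, 0.00, 0.02, -0.06 and 0.07. Of the genes called here and against sham, 1 went in opposite directions (expected 0.385), and 1 was shared with atorvastatin in the same direction, RPL39P36 in both cases. That overlap is too small to compare with chance.

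The combination against hematoma asks what both drugs changed together. KLF2 and RHOB rose, interferon response genes and glucocorticoid receptor targets rose, and the monocyte-attracting chemokine CCL2 fell. KLF2 rose from 7.43 ± 0.243 to 98.7 ± 9.86 FPKM (log2 fold change 3.56, SE 0.08, adjusted p = 5.5e-08) and RHOB from 32.2 ± 0.515 to 132 ± 1.85 FPKM (2.00, adjusted p = 1.5e-07). CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203) fell from 55.1 ± 2.02 to 17.8 ± 0.704 FPKM (-1.57, SE 0.04, adjusted p = 1.5e-07), beside 77.5 ± 0.928 FPKM in sham libraries. RSAD2 (ENSG00000134321, chromosome 2, 6865806 to 6898239) rose from 13.1 ± 0.889 to 44.1 ± 0.0913 FPKM (1.68, adjusted p = 3.7e-07), and TSC22D3 (ENSG00000157514, chromosome X, 107713221 to 107777342) from 12.8 ± 0.278 to 32.3 ± 0.38 FPKM (1.27, adjusted p = 3.1e-07). Other large rises were MT1M at 1.56, CMPK2 at 1.38, LGALS9 at 1.37, IL1RL1 at 1.36, SECTM1 at 1.34, IFI35 at 1.27, HYAL2 at 1.26 and the microRNA gene MIR3682 at 1.39. Other large falls were CTGF at -1.42, APLN at -1.40, G0S2 at -1.24, ESM1 at -1.15, LINC02154 at -1.14, CLDN11 at -1.09, SLC6A6 at -0.94, GCAT and FLJ46906 at -0.90, CXCL8 at -0.83 and the small RNA pseudogene RNU4-47P at -1.23.

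With the combination, 24 of 25 interferon response genes rose (median 0.99, camera adjusted p = 2.0e-27, and 0.0015 with an estimated correlation). IFI6 went from 946 ± 10.7 to 2227 ± 1.54 FPKM, and OAS1 and IFIT2 rose by 1.17 and 1.18. Glucocorticoid receptor targets rose for 15 and fell for 3 of 20 (median 0.34, adjusted p = 5.9e-06). Beside TSC22D3, DUSP1 rose by 0.92, CEBPD by 0.83, FKBP5 by 0.49 (to 84.4 ± 3.27 FPKM, adjusted p = 1.3e-05) and PER1 by 0.26. The KLF2 and KLF4 programme rose for 8 of 10 (median 0.47, adjusted p = 2.1e-06), with KLF6 and THBD at 0.61. NF-kB inflammatory genes fell for 14 and rose for 3 of 22 (median -0.25, adjusted p = 9.8e-05, and 0.076 with an estimated correlation). In that list CXCL1 fell by 0.69 and ICAM1, a leukocyte adhesion molecule, by 0.69 (74.8 ± 0.0473 to 46.2 ± 1.99 FPKM), while CCL5 rose by 0.80.

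Cytosolic ribosomal protein genes fell for 30 of 32 (median -0.24, adjusted p = 6.0e-16, and 0.080 with an estimated correlation), with RPL11 at -0.37 and RPL27 at -0.36. Mitochondrially encoded genes fell for 9 of 13 (median -0.26, adjusted p = 2.3e-06, and 0.058 with an estimated correlation), with MT-CO3 at -0.53, MT-CO1 at -0.38 and MT-CO2 at -0.30, as the mitochondrial share of reads went from 5.88% to 4.77%. Quantile normalization, which fixes the highest values of each library to be equal, set MT-CO1, MT-CO2 and MT-CO3 to 0.00 and ended the list's call (median -0.13, adjusted p = 0.070). DNA replication genes fell for 15 and rose for 1 of 23 (median -0.16, adjusted p = 4.0e-05), with MCM6 at -0.41 and CDC6 at -0.33. G2 and M genes rose for 14 and fell for 3 of 22 (median 0.15, adjusted p = 2.7e-04, and 0.11 with an estimated correlation), with KIF20A at 0.57 and HMMR at 0.43. Fatty acid synthesis genes fell for 7 of 14 (median -0.11, adjusted p = 0.0019, and 0.058 with an estimated correlation), with SCD at -0.40 and FASN at -0.38.

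Endothelial identity genes rose for 8 of 17 (median 0.12, adjusted p = 2.9e-04, and 0.058 with an estimated correlation), with PECAM1 going from 8.65 ± 0.174 to 18.4 ± 0.145 FPKM (1.01) and ICAM2 at 0.69. Metallothioneins rose for 5 of 6 (median 0.71, adjusted p = 9.8e-05, and 0.11 with an estimated correlation), with MT1E going from 124 ± 1.77 to 256 ± 4.11 FPKM and MT1F at 0.95. Heat shock genes rose for 8 and fell for 2 of 16 (median 0.15, adjusted p = 0.015, and 0.087 with an estimated correlation), with HSPB1 at 0.71. Junction genes rose for 9 and fell for 3 of 20 (median 0.09, adjusted p = 0.096). In it CLDN5 rose from 1.06 ± 0.272 to 3.33 ± 0.166 FPKM (1.08, adjusted p = 3.4e-04), ESAM by 0.69 and TJP1 by 0.35, while CDH5 at 0.08 and OCLN at 0.00 were not past the threshold. Cholesterol synthesis genes fell for 6 of 23 (median -0.07, adjusted p = 0.096), with INSIG1 at -0.52 past the threshold and HMGCS1 at 0.00 not. HMOX1 rose by 0.32.

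In all, 3737 genes passed, 1884 higher and 1853 lower, of which 55 rose and 20 fell at least 2-fold, and 12 of 25 lists passed, 4 of them with an estimated correlation. Leaving out hematoma library a or combination library 1 ended the call of PER1 (adjusted p = 0.056 and 0.052). The calls of MIR3682 and RNU4-47P ended with no filter (0.15 and 0.12) and without several of the single libraries (up to 0.16), and that of MT-CO2 with no filter (0.11). Of the genes called here and against sham, 2005 changed in opposite directions and 791 in the same direction. Of the 2005, 1095 were lower with hematoma and rose with the combination (expected 724), such as RSAD2 and IFI6, and 910 went the other way (expected 427), such as MT-CO3. The covariance of the changes was -0.0302, against -0.00611 in simulated groups that the combination left unchanged. In the real data with 1 hematoma library in each comparison, and none shared, the covariance was -0.0213 and the correlation -0.17. Sharing adds nothing to those values, but it gave part of the -0.0302.

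**Figure D2:**
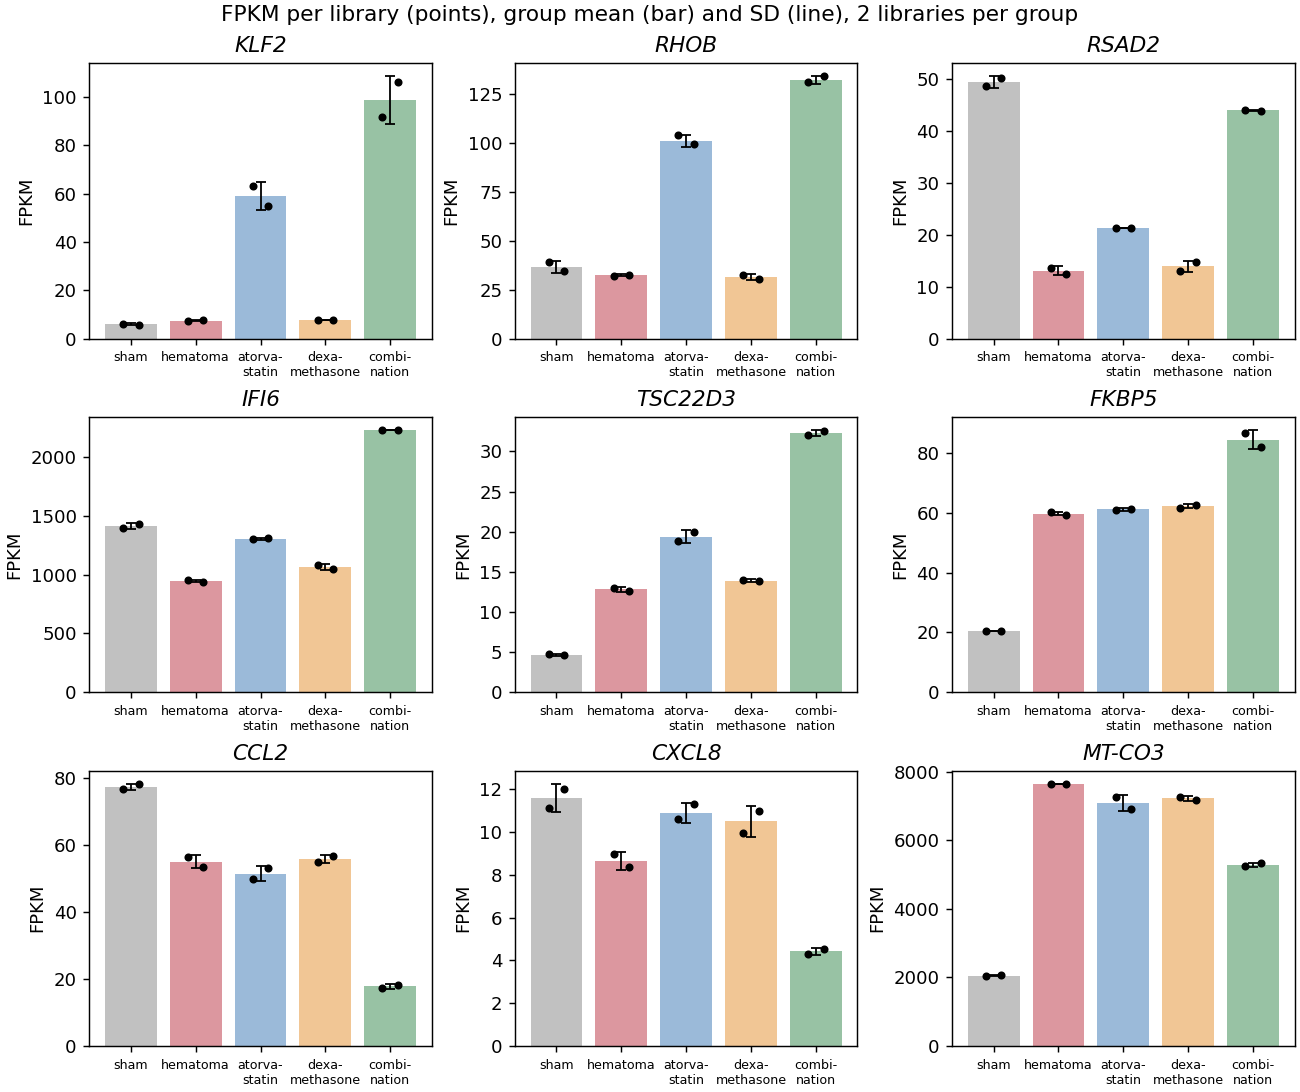
Points are single libraries, bars are the mean FPKM of 2 libraries and lines the SD, for 9 genes in the 5 groups, on axes from 0 FPKM. KLF2 and RHOB are high with atorvastatin and the combination, RSAD2 and IFI6 are low with hematoma, and TSC22D3 and FKBP5 are highest with the combination.

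The combination against atorvastatin asks what dexamethasone, as given in the combination, changed in cells with atorvastatin. NF-kB inflammatory genes fell, and interferon response genes, glucocorticoid receptor targets, the metallothionein gene MT1M and the endothelial adhesion molecule PECAM1 rose. CCL2 fell from 51.5 ± 2.26 to 17.8 ± 0.704 FPKM (log2 fold change -1.48, adjusted p = 9.9e-07). PECAM1 (ENSG00000261371, chromosome 17, 64319415 to 64413776) rose from 8.79 ± 0.36 to 18.4 ± 0.145 FPKM (0.99, adjusted p = 7.8e-06), and TCN2, which carries vitamin B12 (ENSG00000185339, chromosome 22, 30606838 to 30627278), from 30.3 ± 0.38 to 58.2 ± 1.51 FPKM (0.92, adjusted p = 1.5e-06). Other large rises were MT1M at 1.30, RGCC at 1.23, SAP30 at 1.14, RSAD2 at 1.02, HIST1H2AC and MT1E at 0.93, SECTM1 at 0.90, EVA1B at 1.22, CHCHD10 at 0.94, and MIR126, a microRNA gene inside EGFL7, at 2.23. Other large falls were G0S2 at -1.28, CXCL8 at -1.14, CSF3 at -1.10, CXCL1 at -1.06, IL1B at -1.03, CXCL6 at -0.99, STC1 at -0.97, SLC6A6 at -0.94, LINC02154 at -0.91, OPN1SW at -0.87 and RNU6-1091P at -1.81.

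NF-kB inflammatory genes fell for 16 and rose for 1 of 22 (median -0.58, camera adjusted p = 1.2e-11, and 0.037 with an estimated correlation), with ICAM1 at -0.71. Interferon response genes rose for 22 and fell for 1 of 25 (median 0.57, adjusted p = 5.2e-25, and 0.0019 with an estimated correlation), with IFI6, IRF7 and ISG15 at 0.77. Glucocorticoid receptor targets rose for 13 and fell for 3 of 20 (median 0.26, adjusted p = 8.0e-05), with TSC22D3 at 0.71, CEBPD at 0.56, ERRFI1 at 0.54, DUSP1 at 0.52 and FKBP5 at 0.46. Heat shock genes rose for 10 and fell for 1 of 16 (median 0.18, adjusted p = 2.8e-04), with HSPB1 at 0.62. Fatty acid synthesis genes fell for 8 of 14 (median -0.12, adjusted p = 9.7e-04), with FADS1 at -0.26. DNA replication genes fell for 13 and rose for 1 of 23 (median -0.16, adjusted p = 1.1e-05), with MCM6 at -0.39 and RRM2 at -0.30. Mitochondrially encoded genes fell for 8 of 13 (median -0.21, adjusted p = 2.6e-07), as their share of reads went from 5.75% to 4.77%, and quantile normalization ended that call (adjusted p = 0.057).

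Ribosomal protein genes fell for 29 of 32 (median -0.20, adjusted p = 1.6e-16), with RPL27 at -0.35. G2 and M genes rose for 17 and fell for 3 of 22 (median 0.18, adjusted p = 1.5e-06), with KIF20A at 0.67, and endothelial identity genes rose for 8 of 17 (median 0.10, adjusted p = 9.7e-04), with ICAM2 at 0.49. Metallothioneins rose for 5 of 6 (median 0.63, adjusted p = 1.8e-05), and TGF-beta and matrix genes rose for 8 and fell for 4 of 18 (median 0.13, adjusted p = 0.032), with COL1A2 at 0.80, FN1 at 0.50 and TAGLN at -0.47. Unfolded protein and integrated stress response genes rose for 9 and fell for 1 of 19 (median 0.13, adjusted p = 0.036). With an estimated correlation the lists of this paragraph had adjusted p of 0.067, 0.058, 0.058, 0.093, 0.097 and 0.098, in the order given. The KLF2 and KLF4 programme was not past the threshold (median 0.14, adjusted p = 0.052). HMOX1 rose by 0.48, CLDN5 by 0.59, ESAM by 0.54, TJP1 and PER1 by 0.20, and INSIG1 was at -0.38. CDH5 at 0.05, OCLN at 0.04 and HMGCS1 at -0.13 were not past the threshold.

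In all, 2752 genes passed, 1402 higher and 1350 lower, and 13 of 25 lists passed, 7 of them with an estimated correlation. Without atorvastatin library 2, 1707 genes passed, without combination library 2, 1688, and in the groups compared alone, 1566. The call of CLDN5 ended without atorvastatin library 2 (adjusted p = 0.059) and without combination library 1 (0.056), and those of PER1, CHCHD10, EVA1B, MIR126 and TAGLN ended with no filter (0.10, 0.13, 0.070, 0.11 and 0.052). The calls of PER1, CHCHD10, MIR126 and TAGLN also ended without atorvastatin library 1, and those of PER1, CHCHD10, EVA1B and MIR126 without combination library 2. Without atorvastatin library 2 the calls of PER1, CHCHD10 and EVA1B ended (0.14, 0.11 and 0.058), and without combination library 1 that of PER1 (0.14).

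The combination against dexamethasone asks what atorvastatin changed in cells with dexamethasone, at a dexamethasone dose that may differ between the groups. KLF2, RHOB, interferon response genes and endothelial genes rose, and the chemokines CCL2, CXCL8 and CXCL1 fell. KLF2 rose from 7.78 ± 0.0121 to 98.7 ± 9.86 FPKM (log2 fold change 3.50, adjusted p = 1.2e-07), RHOB rose by 2.04, and CCL2 fell from 56 ± 1.22 to 17.8 ± 0.704 FPKM (-1.60, adjusted p = 1.3e-07). Other large rises were RSAD2 at 1.60, MT1M at 1.42, HES4 at 1.34, HYAL2 at 1.31, CMPK2 at 1.27, IFI35 at 1.25, SAMD9L at 1.22, SECTM1 at 1.21, EVA1B at 1.63 and C4orf48 at 1.91. Other large falls were G0S2 at -1.42, LINC02154 at -1.35, CTGF at -1.29, FLJ46906 at -1.12, APLN at -1.11, ESM1 at -1.09, CXCL8 and CLDN11 at -1.08, CXCL1 at -1.05, and the small nucleolar RNAs SNORD69 at -1.56 and SNORA71C at -1.02. FLJ46906 is an antisense gene, and the strand used in counting is not given in the sources used here.

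Interferon response genes rose for 24 of 25 (median 0.93, camera adjusted p = 8.7e-26, and 0.0017 with an estimated correlation), with IFIT2 at 1.09. The KLF2 and KLF4 programme rose for 9 of 10 (median 0.35, adjusted p = 3.0e-06), with THBD at 0.61. Glucocorticoid receptor targets rose for 14 and fell for 3 of 20 (median 0.30, adjusted p = 3.0e-05), with TSC22D3 at 1.16, CEBPD at 0.89, DUSP1 at 0.77, FKBP5 at 0.43 and PER1 at 0.22. NF-kB inflammatory genes fell for 15 and rose for 2 of 22 (median -0.44, adjusted p = 2.8e-06, and 0.041 with an estimated correlation), with CXCL6 at -0.96 and ICAM1 at -0.69. Endothelial identity genes rose for 13 of 17 (median 0.24, adjusted p = 3.4e-06), with PECAM1 at 1.10, ESAM at 0.81, MMRN2 at 0.79 and CLEC14A at 0.54. DNA replication genes fell for 16 and rose for 1 of 23 (median -0.17, adjusted p = 1.7e-05), and fatty acid synthesis genes fell for 7 of 14 (median -0.16, adjusted p = 3.2e-04), with FASN at -0.48.

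Ribosomal protein genes fell for 28 of 32 (median -0.22, adjusted p = 1.7e-12), and mitochondrially encoded genes for 7 of 13 (median -0.21, adjusted p = 1.2e-05), as their share of reads went from 5.7% to 4.77%. G2 and M genes rose for 15 and fell for 3 of 22 (median 0.19, adjusted p = 3.1e-05), and metallothioneins rose for 5 of 6 (median 0.77, adjusted p = 2.1e-04). TGF-beta and matrix genes rose for 10 and fell for 4 of 18 (median 0.19, adjusted p = 0.019), with COL1A2 at 0.83 and TAGLN at -0.68, and junction genes rose for 9 and fell for 4 of 20 (median 0.09, adjusted p = 0.033). With an estimated correlation the lists of this paragraph had adjusted p of 0.099, 0.057, 0.091, 0.13, 0.093 and 0.26, in the order given. CLDN5 rose by 1.05, TJP1 by 0.27, CDH5 by 0.24 and HMOX1 by 0.25, and INSIG1 was at -0.24. OCLN at 0.06 and HMGCS1 at -0.10 were not past the threshold.

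In all, 4038 genes passed, 1950 higher and 2088 lower, of which 49 rose and 21 fell at least 2-fold, and 13 of 25 lists passed, 7 of them with an estimated correlation. The calls of HMOX1, C4orf48, SNORD69 and SNORA71C ended with no filter (adjusted p of 0.063, 0.13, 0.058 and 0.076) and without dexamethasone library 1 (0.10, 0.079, 0.059 and 0.081). Without combination library 2 those of HMOX1, C4orf48 and SNORA71C ended (0.097, 0.10 and 0.078), and that of C4orf48 also without dexamethasone library 2 (0.12) or combination library 1 (0.092). The call of INSIG1 ended without dexamethasone library 2 (0.072) and without combination library 1 (0.051), and that of PER1 without dexamethasone library 2 (0.11) and without either combination library (0.077 and 0.050).

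**Figure D3:**
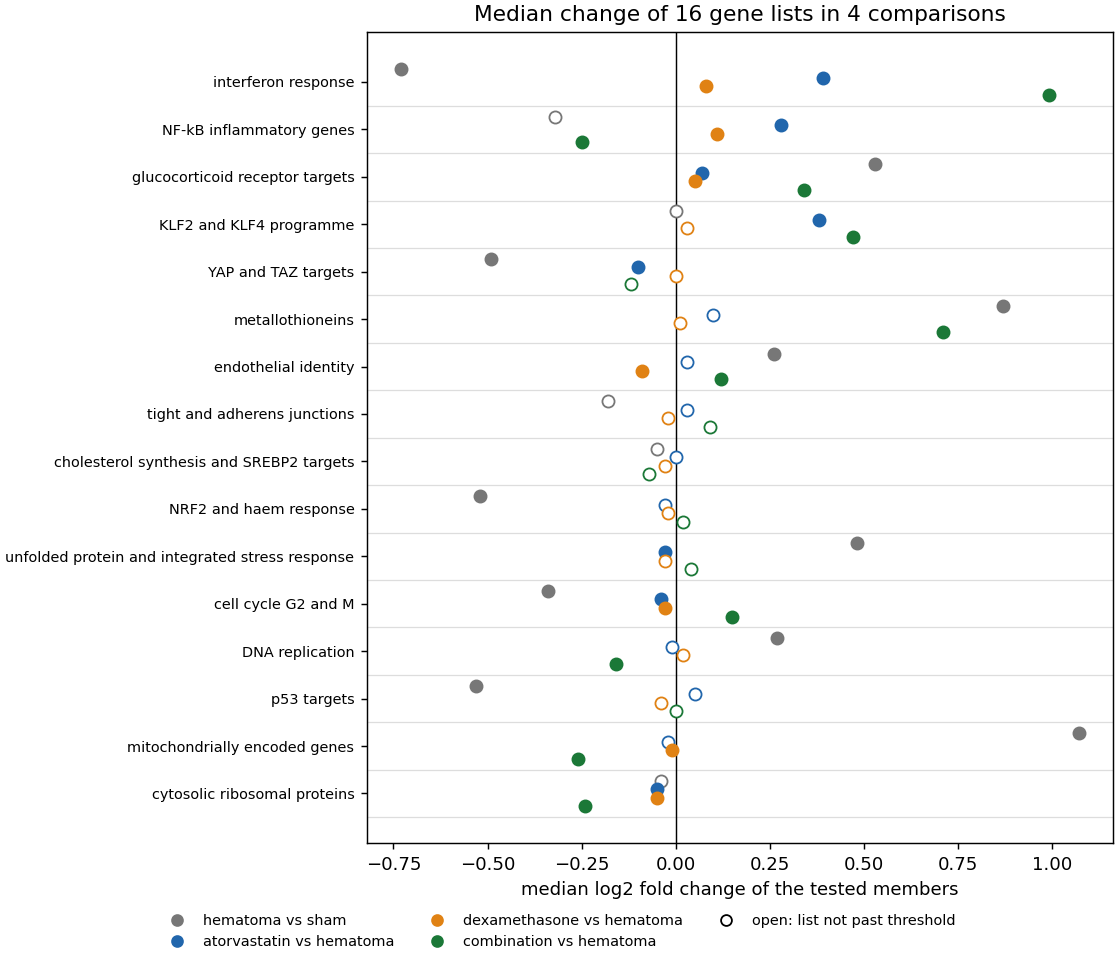
Each point is the median log2 fold change of 1 of 16 gene lists in hematoma against sham libraries and in each treatment against hematoma, with filled points for lists past the threshold with camera and open points for the others. The interferon response list lies at -0.73 with hematoma, 0.39 with atorvastatin, 0.08 with dexamethasone and 0.99 with the combination.

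The interaction asks whether the combination departed from the sum of the log2 changes of the single treatments as given, whose dexamethasone dose may differ from that of the combination. NF-kB inflammatory genes lay below the sum, and interferon response genes and the endothelial adhesion molecule PECAM1 above it. CCL2 departed by -1.5 (SE 0.06, adjusted p = 1.5e-05) and CXCL8 by -1.38 (adjusted p = 1.0e-04), and PECAM1 by 1.08 (adjusted p = 6.7e-05) and TCN2 by 1.05 (adjusted p = 1.7e-05). NF-kB inflammatory genes were below additivity for 15 of 22 and above it for none (median -0.67, camera adjusted p = 8.5e-15, and 0.020 with an estimated correlation). Adjusted over the list alone, 17 were below it. Interferon response genes were above additivity for 22 of 25 (median 0.50, adjusted p = 1.6e-24, and 0.0020 with an estimated correlation), with RSAD2 at 0.93 and ISG15 at 0.66. Endothelial identity genes were above it for 6 of 17 (median 0.19, adjusted p = 8.6e-06), with PECAM1, ESAM at 0.67 and MMRN2 at 0.56, and DNA replication genes below it for 9 of 23 (median -0.16, adjusted p = 1.4e-05).

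Glucocorticoid receptor targets were above additivity for 8 and below it for 3 of 20 (median 0.18, adjusted p = 9.1e-04, and 0.056 with an estimated correlation), with TSC22D3 at 0.59, FKBP5 at 0.40 and NFKBIA at -0.50. TGF-beta and matrix genes were above it for 8 and below it for 1 of 18 (median 0.20, adjusted p = 0.0020, and 0.051 with an estimated correlation), with COL1A2 at 0.92 and FN1 at 0.63. Metallothioneins were above it for 5 of 6 (median 0.75, adjusted p = 3.6e-05, and 0.096 with an estimated correlation), with MT1M at 1.16 and MT1E at 0.88. Ribosomal protein genes were below it for 17 of 32 (median -0.17, adjusted p = 2.1e-11, and 0.10 with an estimated correlation). ICAM1 was at -0.72, HMOX1 at 0.41 and CDH5 at 0.20, all past the threshold, and CLDN5 at 0.57 (adjusted p = 0.063), PER1 at 0.16, TJP1 at 0.13, OCLN at 0.10, INSIG1 at -0.10 and HMGCS1 at -0.23 were not.

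In all, 1579 genes departed from additivity, 828 upwards and 751 downwards, and 14 of 25 lists did, 4 of them with an estimated correlation. The count was 900 without hematoma library a, 875 without hematoma library b, 956 without atorvastatin library 2, 990 without dexamethasone library 1, 904 without dexamethasone library 2 and 985 without combination library 2, and it was 879 with no filter and 2382 with voom. The calls of HMOX1 and CDH5 ended without combination library 2 (adjusted p of 0.064 and 0.067) and without several others, and that of ESAM with no filter (0.052).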

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

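The test of equal depth was planned before its result was seen, and the other tests of explanations in this part were chosen after the results were seen. The results here stand out because the combination differed from the sum of the single treatments, by the interaction test of the report. This held for 1579 genes and 14 gene lists. With 1 library left out it held for 875 to 1177 genes, and with an estimated correlation for 4 lists.

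The first pattern weighed here is the response of glucocorticoid receptor targets. They were already higher in hematoma than in sham libraries for 16 and lower for 4 of 20 (median 0.53). With atorvastatin alone 4 rose and 1 fell (median 0.07). With dexamethasone alone their median stayed at 0.05 on the log2 scale, while with the combination 15 of 20 rose, so that the list departed from additivity by a median of 0.18 (adjusted p = 9.1e-04, and 0.056 with an estimated correlation). Spread between libraries that hid an equal rise is argued against only weakly. In combination against dexamethasone libraries, 14 of the 20 targets were higher and 3 lower, and the list passed camera with an estimated correlation (adjusted p = 0.041). The same libraries set the pattern, so this is no independent test of it. It stays open whether the libraries labelled dexamethasone came from cells with too little active dexamethasone, or with none, which could give the median of 0.05, and no dose is given in the sources used here.

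The other pattern is the departure of NF-kB inflammatory genes from additivity, with a median of -0.67. Scaling is argued against, since the median was -0.68 both after scaling to reads outside the mitochondrial genome and after quantile normalization. The mitochondrial scaling moved the median interaction of all genes only from -0.009 to -0.019. It could thus hardly move the list, and the mitochondrial share is too small a difference to give -0.67. With every library thinned to 16201861 reads the median was -0.66. FPKM values are already scaled for depth, and the libraries held at most 18411429 reads. Thinning could thus hardly move the list, so it decides nothing about depth. A difference in dexamethasone dose or activity between the groups stays open and cannot be told apart from a joint action of both drugs. Chance values of the hematoma libraries, which enter the interaction, can also give part of the departure, and this was not tested. Against hematoma libraries the list's median was 0.28 with atorvastatin, 0.11 with dexamethasone and -0.25 with the combination. In comparisons that take no hematoma mean, it was -0.58 for the combination against atorvastatin and -0.44 against dexamethasone.

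The other lists had median departures on the log2 scale of 0.50 for interferon response, 0.75 for metallothioneins, 0.21 for G2 and M genes, 0.20 for TGF-beta and matrix genes, 0.19 for heat shock response and for endothelial identity, 0.11 for unfolded protein and integrated stress response, and 0.08 for tight and adherens junctions. They were -0.14 for fatty acid synthesis, -0.16 for DNA replication, -0.17 for cytosolic ribosomal proteins and -0.18 for mitochondrially encoded genes. The estimated correlation left 4 of the 14 lists past the threshold: NF-kB, interferon response, endothelial identity and DNA replication. The junction list was not past it with quantile normalization (adjusted p = 0.072) or with voom (adjusted p = 0.056).

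Among single genes the departure upwards was 2.90 for MIR126, 1.79 for EVA1B, 1.33 for PDF, 1.26 for RGCC, 1.16 for MT1M, 1.12 for SAP30, 1.10 for HES4, 1.08 for EBPL and PECAM1, 1.06 for BGN, and 1.05 for HES1 and TCN2. It was 0.93 for RSAD2, 0.66 for ISG15, 0.64 for IRF7 and 0.61 for OAS1 of the interferon list, and 0.67 for ESAM, 0.56 for MMRN2, 0.37 for CLEC14A and 0.20 for CDH5 of the endothelial and junction lists. It was 0.63 for CEBPD, 0.59 for TSC22D3, 0.52 for ERRFI1 and 0.40 for FKBP5 of the glucocorticoid receptor targets. It was 0.92 for COL1A2, 0.63 for FN1, 0.88 for MT1E, 0.52 for HSPB1, 0.41 for HMOX1, 0.76 for KIF20A and 0.56 for HMMR. The departure downwards was -2.32 for RNU6-1091P, -1.5 for CCL2, -1.46 for G0S2, -1.43 for CXCL1 and CSF3, -1.38 for CXCL8, -1.30 for CXCL6, -1.28 for IL1B, -1.18 for STC1, -1.13 for CXCL2 and LINC02154, and -1.0 for FABP5P7. It was -0.72 for ICAM1, -0.61 for CLDN11, -0.58 for CLDN1 and -0.50 for NFKBIA. Leaving out combination library 2 ended the calls of MIR126, EVA1B, PDF, SAP30, HES4, HMOX1, CDH5 and CEBPD, with adjusted p from 0.055 for SAP30 to 0.13 for MIR126. Each other library of the groups that enter the interaction ended at least 1 of these calls when left out, and the sham libraries were not left out here. The setting with no filter ended those of FABP5P7 (adjusted p = 0.070) and ESAM (adjusted p = 0.052). MIR126 and RNU6-1091P are short RNAs and FABP5P7 is a pseudogene, whose reads can belong to other genes.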

How the results depend on the processing

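Scaling to reads outside the mitochondrial genome and voom were chosen after the data were seen. Of 4765 values of named genes under all alternatives, 4513 kept direction and side of the threshold, 220 fell short of it, 13 came past it and 19 changed direction. A pseudocount of 0.1, quantile normalization and scaling outside the mitochondrial genome left each count of genes, lists and overlaps within 1.5 times. With the replicate number as a block and without the hematoma libraries, 2224 genes passed for the combination against atorvastatin and 3615 against dexamethasone, against 2505 and 3869 without the block in the same 8 libraries. The replicate numbers did not pair these libraries, since the differences between replicates correlated between groups at -0.04 to 0.04. For comparisons with hematoma and the interaction: No paired analysis was possible because the names do not show which hematoma sample each hematoma column holds, and the number that ends a column name was not taken as a replicate number. When 1 library is left out, its group's lone library is assumed to vary like the others. Such a fit also has less power. A lower count or an ended call therefore does not show that the library left out was unusual. Depth limits genes of low FPKM: 1 read in a gene of 1 kb is worth up to 0.0617 FPKM.

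With no filter, which tests more genes, 280 genes passed for atorvastatin, 21 for dexamethasone and 879 for the interaction, with 174 and 8 opposite calls for atorvastatin and dexamethasone and 10 shared calls. At a mean of at least 5 FPKM, opposite calls for dexamethasone were 0. In the groups compared alone, which leaves fewer degrees of freedom, 156 genes passed for atorvastatin, 0 for dexamethasone and 1566 for the combination against atorvastatin. Overlaps in that setting came from fits to the 3 groups of both comparisons, which call other genes, with 0 opposite calls for dexamethasone and 3 shared calls. With voom, 986, 92 and 2382 genes passed for atorvastatin, dexamethasone and the interaction, with 14 lists for atorvastatin, 559 and 43 opposite calls for atorvastatin and dexamethasone, and 39 shared calls. The cause of the higher counts with voom was not tested. With an estimated correlation, 7 lists passed for hematoma, 4 for atorvastatin, 1 for dexamethasone, 4 for the combination, 7 and 7 for the combination against atorvastatin and dexamethasone, and 4 for the interaction.

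With 1 library left out, 6092 to 6138 genes passed for hematoma, 193 to 280 for atorvastatin, 0 to 2 for dexamethasone, 2514 to 2727 for the combination, 1688 to 1936 and 2905 to 2998 for the combination against atorvastatin and dexamethasone, and 875 to 1177 for the interaction. Lists ranged from 12 to 13, 8 to 13, 7 to 9, 12 to 13, 12 to 15, 13 to 14 and 13 to 14 in the same order. Opposite calls ranged from 125 to 215 for atorvastatin, 0 to 2 for dexamethasone and 1338 to 1754 for the combination, and shared calls from 0 to 2.

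Among values that changed direction, only those of MT-CO1, MT-CO2 and MT-CO3 were past the threshold as reported. They went to 0.00 for the combination against hematoma with quantile normalization, which makes the highest values of all libraries equal. For the same comparison HMGCS1 was at -0.01 with quantile normalization and with scaling outside the mitochondrial genome, and OCLN at -0.01 with that scaling. Leaving out 1 library gave ranges across 0. For atorvastatin they were -0.11 to 0.02 for OCLN and -0.02 to 0.07 for ICAM1. For dexamethasone they were -0.11 to 0.16 for CLDN5, -0.13 to 0.00 for OCLN, -0.03 to 0.09 for PER1, -0.02 to 0.03 for ICAM1, -0.26 to 0.09 for CXCL10 and -0.14 to 0.00 for IRF1. For the combination they were -0.06 to 0.07 for OCLN and -0.09 to 0.09 for HMGCS1. As reported, these genes lay within 0.08 of 0 in those comparisons.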

Other observations

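The enrichment of gene ontology terms and the tests of the interferon level and a handling difference and the bound on cholesterol genes were chosen after the results were seen, and the tests of depth and of mitochondrial reads were planned before. Beyond the lists of the report, genes that rose with hematoma were enriched for rRNA processing and for the making of mitochondrial proteins. They held 81 of 134 genes of rRNA processing (32.9 expected, adjusted p = 1.1e-15) and 55 of 79 of mitochondrial translational elongation (19.4 expected, adjusted p = 2.4e-14). They held 23 of 32 of tRNA aminoacylation (7.87 expected, adjusted p = 8.5e-06) and 13 of 16 of the glycolytic process (3.93 expected, adjusted p = 9.0e-04). The planned hypoxia and glycolysis list did not rise, with 6 higher and 10 lower of 19 (median -0.30, camera adjusted p = 0.99). Nor did cytosolic ribosomal proteins, with 1 higher and 14 lower of 32 (median -0.04, camera adjusted p = 0.39). The mitochondrial share of reads rose in the same libraries, from 3.53% to 5.88%. Genes that fell with hematoma held 33 of 41 genes of interferon-gamma signaling (16.1 expected, adjusted p = 1.1e-04).

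With atorvastatin, the genes that fell held 9 of 89 of extracellular matrix organization (adjusted p = 0.0078) and 5 of 32 of muscle contraction (adjusted p = 0.029). Those that rose held 24 of 142 of the inflammatory response (adjusted p = 1.9e-09). As for the NF-kB list, part of that rise can come from the hematoma libraries, which the dexamethasone comparison shares. With the combination, the genes that fell against hematoma held 95 of 223 of translation (adjusted p = 7.0e-17) and 63 of 134 of rRNA processing (adjusted p = 2.4e-13). Those that rose held 84 of 255 of neutrophil degranulation (adjusted p = 1.6e-07), a term with many lysosomal and membrane proteins of other cells. Against atorvastatin, those that rose held 9 of 14 genes annotated to positive regulation of transcription of Notch receptor targets (adjusted p = 0.0013).

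Interferon response genes fell with hematoma and rose with treatment, and a hypothesis was that the combination brought them back to the sham level. Their median log2(FPKM + 1) was 6.38 in sham, 5.40 in hematoma, 5.80 in atorvastatin, 5.52 in dexamethasone and 6.48 in combination libraries. The median difference of combination against sham was 0.21, 0.01 beyond the bound of 0.2 set for a return and within the standard error of 0.05 over the members of that bound, with 15 of 25 members higher and 2 lower. Whether the list's median lay within that bound was therefore left open, also because the members are not independent replicates. For the 15 members called higher, a return to the sham level itself is argued against. In the whole, 6977 genes differed between combination and sham libraries.

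KLF2 and RHOB rose with atorvastatin, while the cholesterol synthesis list did not pass the threshold. For each of the 23 cholesterol synthesis genes the upper bound of the 95% interval lay under a 1.5-fold rise, with 0.40 on the log2 scale as the highest. The time of harvest is not given in the sources used here.

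Sham libraries listed 22678.5 ± 19.09 genes above 0 FPKM and hematoma libraries 21230.0 ± 55.15 (SD, n = 2), a difference of 1448.5. Deeper sequencing of sham libraries is argued against, since the difference was 1352 at equal reads. Mitochondrial reads in the place of others are argued against by a difference of 1328 at 15281756 reads outside the mitochondrial genome per library. There were 3415 genes with reads in sham and none in hematoma libraries, with a median of 2 reads over both sham libraries, and 1854 genes the other way. These 3415 genes took 0.0227% of the sham reads and 26.2% of them were protein coding, so a handling or library difference, such as more genomic DNA or unspliced RNA, cannot be told apart from a change in the cells, since both give such reads.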
